A study of Mus musculus with 145 samples.

How the data were processed

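T cell receptor beta (TCRβ) rearrangements were measured in genomic DNA of single cell suspensions from perfused mammary tissue, amplified for a TCRβ library and sequenced in paired reads, per the labels' protocols. The samples came from MMTV-PyMT mice, in which the polyoma middle T antigen drives mammary tumours, and from FVBN mice labelled WTNT, an abbreviation the labels do not spell out. Every sample carries the cell type label primary tumour, those from FVBN mice included. Per the labels' protocols, PLX (PLX3397, pexidartinib, an inhibitor of the macrophage growth factor receptor CSF1R) was given in chow from day 80 at 40 mg/kg per day, and PTX (paclitaxel) from day 85 at 10 mg/kg every 5 days. Anti-PD-1 antibody (aPD-1) was given from day 87 at 1.0 mg and then 0.5 mg per mouse every 5 days. Other arms are labelled aPD-L1, for which the protocols give no antibody or dose. The arm given all of PLX, PTX and aPD-1 is divided into samples labelled R and NR, which the labels do not spell out. The labels name 145 samples and a file existed for 118 of them. The other 27 samples were not analysed here.

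The deposited file of each sample lists 1 clonotype per row, with its V and J segments, its complementarity-determining region 3 (CDR3) as nucleotides and amino acids, and its abundance in several units. The authors' read count per clonotype is a whole number, per the file headers and the values. The deposited normalized value is a score, called a normalized clone count in the file headers. It is the read count multiplied by the authors with a factor for each pair of V and J segment and rounded to a whole number. In 787 combinations of library and V-J pair with at least 2 clonotypes of 100 or more reads, the factor varied by at most 0.0098. The factors ran from 0.346 to 14.6. Rounding left 4753 of 113527 rows (4.19%) with a normalized value of 0. The deposited fraction columns give each clonotype's share of all reads or of the kept rows, per the file headers. The share of reads kept in the files ran from 74.9% to 100% per library, from the first of these fractions. The files held 21 V and 13 J segments and 0 rows marked as not productive, and TRBV31 occurred in 0 files. The aligner, the reference build and the rule by which rows were removed are not given in the sources used here.

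From the normalized values 3 measures were computed per library. Clonality is 1 minus the Shannon entropy divided by the log of the number of clonotypes, and is 0 for a perfectly even repertoire. The number of clonotypes was counted at the nucleotide level and analysed as log2. The expanded share is the percent of normalized values in clonotypes of at least 1% each. This cut is fixed, so the expanded share depends on the number of clonotypes in a library as well as on evenness. Segment use was the percent of clonotypes carrying a segment, each clonotype counted a single time. Fixed lists of segments were summed: NKT-associated (TRBV13-2, TRBV29, TRBV1), MAIT-associated (TRBV19, TRBV13-2, TRBV13-3), mouse mammary tumour virus superantigen-reactive segments, the 9 V segments inside the genomic deletion of the Vβ-a haplotype of some Swiss-derived strains (below, the deletion list: TRBV12-1, TRBV12-2, TRBV13-1, TRBV13-2, TRBV13-3, TRBV14, TRBV15, TRBV16 and TRBV17), and the TRBJ2 cluster. The NKT-associated and MAIT-associated segments are not specific for those cells, and TCRβ DNA carries no marker of other cell types.

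The 13 comparisons were set before the data were examined, as were the measures, the lists, the tests and most of the alternatives. Each measure was compared by a two-sided permutation test of the difference of group means, by exact enumeration where a group had fewer than 10 mice and otherwise with 100000 resamples, where 2e-05 is the smallest p possible. The p-values were adjusted by the Benjamini-Hochberg method over the 13 comparisons of a measure, with a threshold of 0.05. Segment use was compared with limma 3.58.1 in R 4.3.3 on log2 of the percent plus 0.1, for segments with a mean of at least 0.1%, with all MMTV-PyMT groups of d105 in 1 fit. Shared clonotypes, defined by V segment, CDR3 amino acids and J segment, were compared by Fisher's exact test where found in at least 25% of the mice. Overlap between mice was the Morisita-Horn index, tested with 10000 resamples or exactly where fewer arrangements existed. The interaction of antibody and PLX was tested by permuting residuals of the additive model. The remaining computation used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Named items followed a rule set in advance. Per comparison these were the segments past the threshold, or else the 3 with the smallest p, and the shared clonotypes past the threshold, at most 5, or else the 1 with the smallest p. Over the d105 MMTV-PyMT mice they were the 10 most used segments, the 10 most shared clonotypes and the most abundant clonotype of each group. Items named outside this rule are said to have been chosen after their values were seen.

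The permutation test, the limma step and Fisher's test were tested on simulated data. For 7 mice against 7, a shift of 2 SD was called in 92% of 200 simulations and no shift in 5.5%. For PTX+aPD-L1 against PTX, with the spread between real samples, limma recovered 66% of segments changed 2-fold and 69.3% of those changed 1.5-fold, among 14 segments of which 6 were changed, with 0% in the wrong direction. In 10% of the simulations without a change at least 1 segment was called. For Fisher's exact test, 50 simulations of 14 against 10 mice called 95.5% of clonotypes in 90% against 10% of mice and 0.8% of unchanged ones. A first version of the limma simulation used an assumed spread and recovered fewer segments than the minimum set for it. The spread was then estimated from the samples and that minimum was dropped, so the recovery is given here as it came out.

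Depth ran from 193 to 1516226 reads per library (median 6930), and 55 of the 118 libraries held fewer than 500 clonotypes. Read counts stand for PCR products without molecular identifiers, so the exact (Clopper-Pearson) 95% intervals given for single libraries cover counting error only. The labels give no sequencing batch. They give animal numbers, which were divided in advance into blocks A (below 33500), B (33500 up to 35000), C (35000 up to 38000) and D (from 38000), and these blocks differed in depth. Alternatives were read counts in place of the normalized values, clonotypes of at least 2 reads, merging by amino acids, thinning every library to 2541 reads (12 libraries left out, mean of 20 draws), libraries of at least 500 clonotypes, medians, the Gini index, the 10 most abundant clonotypes, permutation within blocks, each block alone, other pseudocounts, segment filters and fits, other definitions of a shared clonotype, the Jaccard index and the pooling of FVBN days. Chosen after seeing the data were the omission of the deletion-list segments (for the lists too), the omission of the clonotype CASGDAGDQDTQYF (for the overlap too), the files' other normalized value, the pairs of deletion-list omission with thinning or with blocks, the lists, the F tests over all arms and the shared clonotypes within blocks, and leaving out each replicate outside day 95. Thinned measures were computed from the reads drawn and not from normalized values, so thinning changes the unit as well as the depth. The planned comparison of rows not marked productive had no rows to run on. The samples from groups of 1 library (FVBN at d105, untreated MMTV-PyMT at d80) entered no comparison except where FVBN days were pooled.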

Results

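TCRβ repertoires of 118 libraries were compared to see how treatment with the CSF1R inhibitor PLX, paclitaxel and antibodies against PD-1 or PD-L1, the receptor and ligand of a T cell checkpoint, went with the T cells of MMTV-PyMT mammary tumours. At d105 (age in days) there were files for 10 untreated mice, 14 given PTX, 10 given PLX, 15 given PLX+PTX, 7 given aPD-L1, 10 given PTX+aPD-L1, 13 given PLX+PTX+aPD-L1, 9 given PTX+aPD-1, and 14 given PLX+PTX+aPD-1, of which 7 were labelled R and 7 NR. At d95 there were 3 mice given PTX and 4 given PLX+PTX+aPD-1. FVBN mice were represented by 7 libraries of d80 and 1 of d105, and untreated MMTV-PyMT mice of d80 by 1. Libraries held from 46 to 17300 productive clonotypes (median 542) in 193 to 1516226 reads. Median reads were 5764 in the 67 libraries of block A, 6717 in the 26 of block B, 267330 in the 10 of block C and 5259 in the 7 of block D.

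Over the 102 d105 MMTV-PyMT mice the most used V segments were TRBV24 (18% ± 5.17 of clonotypes, SD), TRBV1 (16.8% ± 3.70), TRBV5 (10.8% ± 2.61) and TRBV3 (10.2% ± 3.20), followed by TRBV2 (9.54% ± 2.48). The most used J segments were TRBJ2-7 (21.3% ± 3.46), TRBJ2-5 (13.5% ± 2.49), TRBJ2-1 (12.7% ± 2.43), TRBJ2-3 (12.1% ± 2.21) and TRBJ2-4 (9.54% ± 1.68). The 9 deletion-list segments were rare. Their mean was 10.5% ± 5.03 of clonotypes in untreated tumours (n = 10) and 8.30% ± 4.80 in FVBN mice of d80 (n = 7), and the range over all libraries was 0.325% to 30.4%. Block C had a median of 0.953% and block D of 0.833%, against 8.13% in block A and 9.26% in block B.

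Abundant clonotypes did not use V segments as the whole repertoire did, and the segments depended on how abundance was counted. Mice with few abundant clonotypes were left out, which leaves 85 mice by normalized values and 72 by reads. Normalized values hold a factor for each V-J pair, so a segment with large factors reaches 1% more readily. A difference seen by normalized values alone cannot be told apart from this factor. By normalized values, TRBV4, chosen like TRBV26 after its values were seen, made up 26.4% of the clonotypes of at least 1%, against 5.47% of all clonotypes (higher in 75 of 85 mice, permutation p = 2e-05, the smallest possible, adjusted p = 5e-05 over 15 segments). TRBV26 made up 10.6% against 3.79% (57 of 85 mice, adjusted permutation p = 5e-05), and TRBV1 5.35% against 16.7% (lower in 80 of 85 mice, adjusted permutation p = 5e-05). By reads, TRBV4 made up 5.05% of abundant clonotypes against 5.45% of all, TRBV26 2.84% against 3.73% (higher in 25 of 72 mice) and TRBV1 18.7% against 16.4%. TRBV24 made up 27.4% against 17.9% by reads (higher in 55 of 72 mice, adjusted permutation p = 0.0002). By normalized values TRBV24 made up 20.7% against 18.2% (higher in 36 of 85 mice, adjusted permutation p = 0.236). TRBV5 was lower by reads, at 4.45% against 10.8% (lower in 60 of 72 mice, adjusted permutation p = 0.00015).

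**Figure D1:**
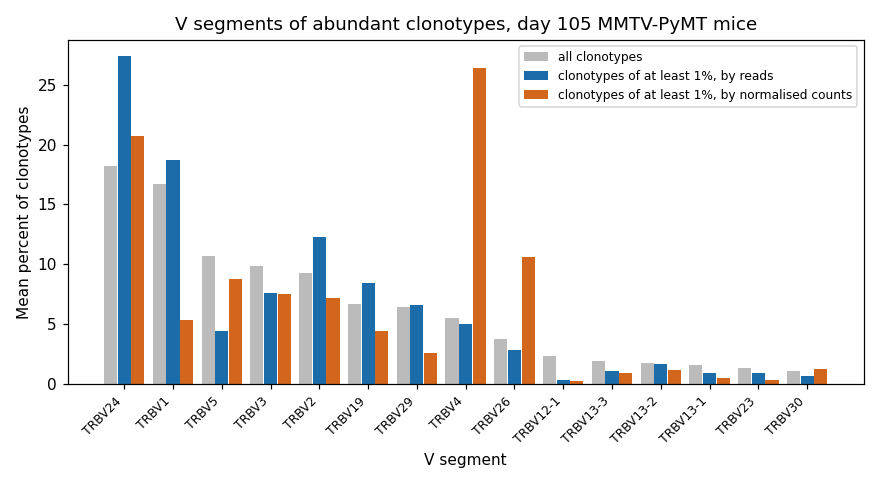
Mean percent of clonotypes per V segment over d105 MMTV-PyMT mice, for all clonotypes (grey) and for those of at least 1% by reads (blue, 72 mice) or by normalized values (orange, 85 mice). TRBV4 reaches 26.4% by normalized values and 5.05% by reads.

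The amino acid clonotypes found in the most mice were TRBV12-1 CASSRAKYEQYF TRBJ2-7 (53 of 102 mice, at most 2.41% of a library), TRBV13-3 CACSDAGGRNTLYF TRBJ2-4 (45 mice) and TRBV13-3 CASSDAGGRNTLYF TRBJ2-4 (43 mice), all of deletion-list segments. The next were TRBV1 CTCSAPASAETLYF TRBJ2-3 (27 mice), TRBV2 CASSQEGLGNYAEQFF TRBJ2-1 (26 mice) and TRBV4 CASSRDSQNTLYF TRBJ2-4 (23 mice). TRBV5 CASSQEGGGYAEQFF TRBJ2-1 and TRBV13-3 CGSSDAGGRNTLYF TRBJ2-4 were each in 23 mice, and TRBV1 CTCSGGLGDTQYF TRBJ2-5 and TRBV3 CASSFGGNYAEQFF TRBJ2-1 each in 21. The nucleotide sequence of the most abundant clonotype of a group was in 1 file in 10 of the 15 groups. Among these were TRBV3 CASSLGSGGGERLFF TRBJ1-4 in PTX replicate 7 (26.8% of normalized values, 9.69% of reads, exact 95% interval 9.27% to 10.1%) and TRBV3 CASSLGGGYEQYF TRBJ2-7 in PTX+aPD-L1 replicate 6 (17.6% of normalized values, 21.2% of reads, interval 20.9% to 21.6%), whose amino acid clonotype was in 6 libraries. In 4 groups the top clonotype was TRBV13-2 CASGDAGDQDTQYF TRBJ2-5, which had the same nucleotide sequence in 20 libraries, FVBN included. It reached 65.0% of normalized values in R replicate 7 (58.3% of reads, interval 56.7% to 59.9%) and 39.6% in PLX replicate 2 (39.7% of reads, interval 38.2% to 41.2%).

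**Figure D2:**
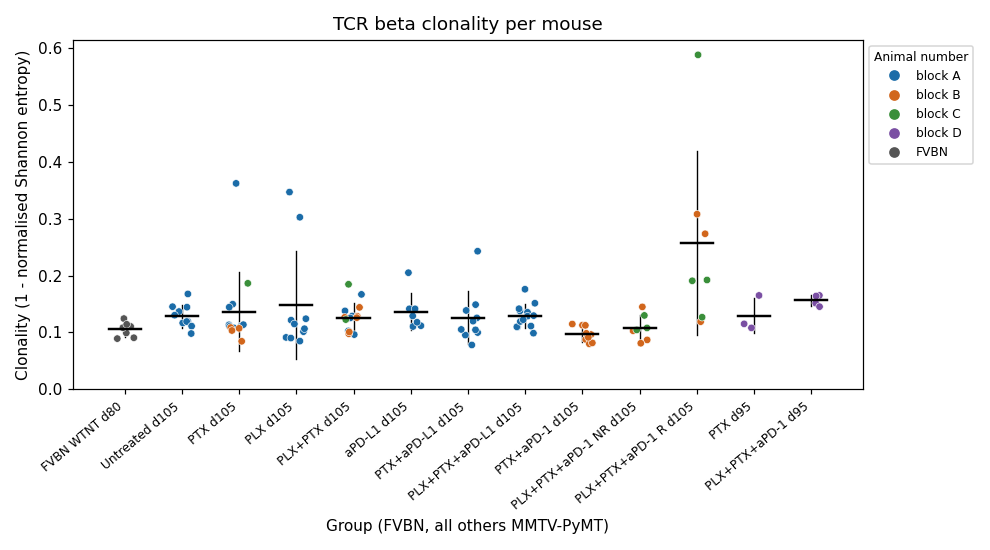
Clonality (no unit) per mouse, with 1 point per library coloured by block of animal numbers, the mean as a horizontal bar and 1 SD as a vertical line. All 7 mice labelled R lie above the NR mean of 0.108, and R replicate 7 lies at 0.588.

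Across the 9 treatment arms of d105, R and NR taken as 1 arm, the number of clonotypes differed (permutation F = 3.63, adjusted p = 0.00351, n = 102), as did the expanded share (F = 2.33, adjusted p = 0.0377). Clonality did not pass (F = 1.34, permutation p = 0.205). With arms permuted within blocks, the only alternative and one chosen after seeing the data, the number of clonotypes passed (permutation adjusted p = 0.0241) and the expanded share did not (permutation p = 0.105, adjusted p = 0.141). In that test 6 of the 9 arms lie in 1 block each, among them PLX, whose libraries were unlike the rest of block A. The antibody and PLX interaction passed for 0 of 6 tests by permutation of residuals, with 1 at an unadjusted p under 0.05. That was clonality for aPD-1, where the antibody's difference was -0.0391 without PLX and 0.0566 with it (permutation p = 0.0165, adjusted p = 0.0991). The effects of antibody with and without PLX below are therefore not shown to differ.

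Untreated MMTV-PyMT tumours of d105 held fewer clonotypes than the mammary tissue of FVBN mice of d80, with more of the repertoire in abundant clonotypes. Mean log2 clonotypes was 9.01 ± 0.64 (SD, n = 10) against 10.36 ± 0.70 (n = 7), with 10 of 10 tumours below the FVBN mean (exact permutation adjusted p = 0.00535). The expanded share was 24.1% ± 11.6 against 7.37% ± 5.29 (10 of 10 tumours above, exact permutation adjusted p = 0.0112), and clonality was 0.129 ± 0.0202 against 0.105 ± 0.0129 (9 of 10 above, exact permutation adjusted p = 0.0404). No segment passed limma's test (0 of 33, 2 at unadjusted p under 0.05). The smallest p belonged to TRBJ1-4 (3.55% ± 0.847 against 2.62% ± 0.647), TRBV12-2 (0.142% ± 0.243 against 0.405% ± 0.298) and TRBV4 (4.84% ± 1.88 against 6.58% ± 1.09). With its fixed cut, the expanded share is not independent of the number of clonotypes. The groups differ in age as well as in genotype, and in depth, with median reads of 5007 in tumours and 14640 in FVBN libraries. Thinned to the same reads the difference in log2 clonotypes was -0.79, against -1.36 as reported. It missed the threshold among libraries of at least 500 clonotypes (-0.91, exact permutation adjusted p = 0.0559, range over alternatives 0.00238 to 0.0559), as did the expanded share there (8.79 percentage points) and when thinned. By read counts the adjusted exact permutation p was 0.0521 for the expanded share and 0.232 for clonality, within ranges over all alternatives of 0.00772 to 0.0909 and 0.0227 to 0.504.

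PTX alone went with no difference past the threshold in clonality (0.136 ± 0.0696, n = 14, against 0.129 ± 0.0202 untreated, n = 10), log2 clonotypes (9.18 ± 1.09 against 9.01 ± 0.64) or expanded share (24.8% ± 13.9 against 24.1% ± 11.6). Segment use passed for 0 of 33 segments by limma, with 1 at unadjusted p under 0.05, TRBJ1-7 (0.285% ± 0.242 against 1.11% ± 1.22). TRBV20 was at 0.923% ± 0.507 against 0.517% ± 0.502 and TRBJ2-3 at 12.3% ± 2.45 against 14.0% ± 2.29. The TRBJ2 cluster, the segments of the second diversity and joining group, was at 77.5% ± 2.52 against 74.4% ± 2.71 (13 of 14 above, permutation adjusted p = 0.123). PLX+PTX did not pass either, against untreated or against PTX, with clonality at 0.126 ± 0.0256, log2 clonotypes at 8.95 ± 1.40 and expanded share at 26.7% ± 20.3 (n = 15). Against untreated, 0 of 33 segments passed and 3 had an unadjusted limma p under 0.05, TRBJ1-4 (2.27% ± 1.10 against 3.55% ± 0.847), TRBJ1-7 (0.522% ± 1.17 against 1.11% ± 1.22) and TRBV24 (16.6% ± 4.66 against 20.1% ± 4.30). Against PTX, 0 of 33 passed and 0 had an unadjusted limma p under 0.05. The smallest p belonged to TRBV14 (0.906% ± 0.769 against 0.552% ± 0.746), TRBV2 (9.06% ± 2.58 against 10.6% ± 2.26) and TRBV20 (0.715% ± 0.663 against 0.923% ± 0.507).

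Tumours of mice given PLX alone held fewer clonotypes than untreated ones, and the MAIT-associated segments took a larger share of them, but the PLX libraries also stand apart from the rest of their block. Log2 clonotypes was 8.04 ± 0.83 against 9.01 ± 0.64 (n = 10 and 10, medians of 196 and 596 clonotypes, 8 of 10 below the untreated mean, permutation adjusted p = 0.0494). The MAIT-associated list rose from 8.96% ± 1.98 to 13.6% ± 2.44 of clonotypes (10 of 10 above, permutation adjusted p = 0.00624). Its members are TRBV19 (8.61% ± 2.87 against 5.75% ± 1.56), the V segment shared by many MAIT cells, and the deletion-list segments TRBV13-2 (2.54% ± 1.62 against 1.40% ± 1.06) and TRBV13-3 (2.42% ± 1.68 against 1.81% ± 1.47), of which 0 passed alone. Without the deletion-list segments, an alternative chosen after seeing the data, the list was at 9.77% ± 2.86 against 6.42% ± 1.69 and did not pass (permutation adjusted p = 0.0827, range over alternatives 0.00576 to 0.0827). TRBV19, TRBJ2-3 (11.9% ± 1.06 against 14.0% ± 2.29, 10 of 10 below) and TRBV24 (16.7% ± 3.53 against 20.1% ± 4.30) had the smallest limma p, with 0 of 33 segments past the threshold and 0 at unadjusted p under 0.05. Of 10 shared clonotypes tested, 5 passed by Fisher's exact test. TRBV12-1 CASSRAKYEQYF was in 0 of 10 PLX and 9 of 10 untreated mice (adjusted p = 0.00119) and TRBV13-3 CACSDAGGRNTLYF in 0 and 7 (adjusted p = 0.0103). TRBV13-2 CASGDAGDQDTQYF was in 7 of 10 PLX and 0 of 10 untreated mice (Fisher's exact adjusted p = 0.0103), and TRBV13-1 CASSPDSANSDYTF and TRBV17 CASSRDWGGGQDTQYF each in 6 and 0 (adjusted p = 0.0217). All 5 use deletion-list segments. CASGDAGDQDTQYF had 1 nucleotide sequence over its 20 libraries, and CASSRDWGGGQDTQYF also had 1 over all files. Among the 141 clonotypes in at least 10% of the mice, 1 passed by Fisher's exact test. Clonality was 0.148 ± 0.0943 against 0.129 ± 0.0202, and without the deletion-list segments, an alternative chosen after seeing the data, it was lower in PLX (difference -0.0262, permutation adjusted p = 0.0233, range over alternatives 0.0233 to 0.866). The difference in clonotypes missed the threshold with clonotypes of at least 2 reads (-0.69, permutation adjusted p = 0.211, range over alternatives 0.0353 to 0.929) and in 15 of 20 omissions of a replicate. PLX libraries also had a lower median share of clonotypes with a single read (17.9% against 31.9%) and more reads per clonotype (median 26.7 against 9.40). In both they were nearer to the 26 libraries of block B (20.4% and 21.8) than to the other 57 of block A (31.6% and 10.0). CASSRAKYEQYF, compared this way after its values were seen, was in 54 of those 57 libraries, in 0 of 10 PLX libraries and in 0 of 26 of block B. Log2 clonotypes averaged 7.97 ± 0.85 in block B and the MAIT-associated list 11.2% ± 4.20. A difference in handling that the labels do not give cannot be told apart from PLX in this comparison.

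**Figure D3:**
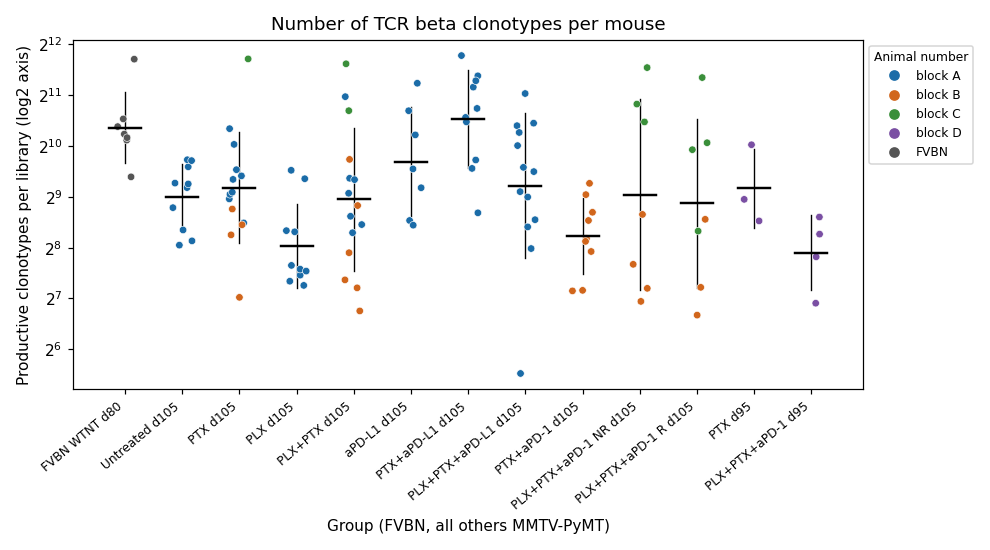
Number of productive clonotypes per library on a log2 axis, with 1 point per mouse coloured by block of animal numbers, the mean of log2 values as a horizontal bar and 1 SD as a vertical line. The median is 196 clonotypes for PLX, 596 for untreated and 1613 for PTX+aPD-L1.

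With aPD-L1 alone the J segment TRBJ2-3 fell to 10.2% ± 2.17 of clonotypes from 14.0% ± 2.29 in untreated tumours (log2 difference -0.47, SE 0.13, 7 of 7 mice below, limma adjusted p = 0.0241), the 1 of 33 segments past the threshold and the 1 with an unadjusted p under 0.05. TRBV4 (6.4% ± 1.29 against 4.84% ± 1.88) and TRBJ2-1 (14.1% ± 2.63 against 11.8% ± 1.78) came next and did not pass. Clonality (0.137 ± 0.0327, n = 7), log2 clonotypes (9.69 ± 1.07) and expanded share (19.1% ± 10.4) did not pass by exact permutation. The limma call ended with the 2 groups alone in the fit (adjusted p = 0.173, range over alternatives 0.00594 to 0.786).

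Adding aPD-L1 to PTX went with more clonotypes and a smaller share of the repertoire in abundant ones. Log2 clonotypes was 10.54 ± 0.96 (n = 10) against 9.18 ± 1.09 with PTX (n = 14), medians of 1613 and 538 clonotypes (9 of 10 above, permutation adjusted p = 0.0356). The expanded share was 10.4% ± 8.44 against 24.8% ± 13.9 (9 of 10 below, permutation adjusted p = 0.0112), while clonality did not pass (0.126 ± 0.0461 against 0.136 ± 0.0696). No segment passed (0 of 33 by limma, 2 at unadjusted p under 0.05). TRBV29 was at 8.16% ± 1.33 against 6.15% ± 1.76 (10 of 10 above, limma adjusted p = 0.253), TRBV13-1 at 0.623% ± 0.944 against 1.46% ± 0.887 and TRBV13-2 at 0.687% ± 0.740 against 1.24% ± 0.967. Within block A, the only block with both arms, the difference in log2 clonotypes was 1.17 (permutation within blocks, adjusted p = 0.0684) and that in expanded share -12.4 percentage points (adjusted p = 0.129). The expanded share also missed the threshold by read counts (-10.6, permutation adjusted p = 0.338, range over alternatives 0.0123 to 0.626). So it did when thinned (-11.2, exact permutation adjusted p = 0.350) and by the 10 most abundant clonotypes (-7.22, permutation adjusted p = 0.215). Its fixed cut ties it to the number of clonotypes, so it is not a separate line of evidence. With PLX+PTX as background, aPD-L1 went with no difference past the threshold in log2 clonotypes (9.22 ± 1.43, n = 13, against 8.95 ± 1.40, n = 15), expanded share (24.4% ± 22.0 against 26.7% ± 20.3) or clonality (0.129 ± 0.0206 against 0.126 ± 0.0256). Of 33 segments, 0 passed limma's test and 3 had an unadjusted p under 0.05, TRBV5 (9.11% ± 3.16 against 11% ± 1.98), TRBV26 (3.30% ± 1.55 against 4.20% ± 0.969) and TRBJ1-3 (1.76% ± 0.822 against 2.38% ± 1.07). TRBV12-1 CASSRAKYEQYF was in 12 of 13 mice against 7 of 15 (Fisher's exact adjusted p = 0.110), and within block A in 12 of 13 against 7 of 7.

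Adding aPD-1 to PTX went with lower clonality and less use of NKT-associated segments. Log2 clonotypes was lower, at 8.23 ± 0.75 against 9.18 ± 1.09, and did not pass (exact permutation adjusted p = 0.092). The expanded share was higher, at 29.6% ± 21.8 against 24.8% ± 13.9, and did not pass either (exact permutation adjusted p = 0.766). Clonality was 0.0973 ± 0.0135 (n = 9) against 0.136 ± 0.0696 with PTX (n = 14), with 9 of 9 below the PTX mean (exact permutation adjusted p = 0.0404). The NKT-associated list fell from 25.2% ± 3.43 to 20.1% ± 2.82 of clonotypes (9 of 9 below, exact permutation adjusted p = 0.0147). Of its members, TRBV1 was at 13.3% ± 1.85 against 17.8% ± 3.33 (9 of 9 below, limma adjusted p = 0.0934), TRBV29 at 5.45% ± 1.71 against 6.15% ± 1.76 and TRBV13-2, the segment of many NKT cells, at 1.30% ± 0.923 against 1.24% ± 0.967. With TRBV1, TRBV15 (1.35% ± 1.98 against 0.297% ± 0.273) and TRBV30 (1.57% ± 0.953 against 0.903% ± 0.748) had the smallest limma p, and 0 of 33 passed, with 1 at unadjusted p under 0.05. TRBV12-1 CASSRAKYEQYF was in 0 of 9 mice against 9 of 14 (Fisher's exact adjusted p = 0.0234). All 9 PTX+aPD-1 libraries belong to block B, which holds 4 of the PTX libraries. Within it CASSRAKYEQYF was in 0 of 9 against 0 of 4 mice, so its call has no counterpart there (exact permutation p = 1, a test chosen after seeing the data). The difference in clonality within it was -0.00364 (exact permutation adjusted p = 0.779) and that in NKT-associated segments -3.27 percentage points (exact permutation adjusted p = 0.447). Without PTX replicate 7 the difference in clonality was -0.0218 and the call ended, as it did with 7 other single omissions (exact permutation adjusted p at most 0.073).

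The PLX+PTX+aPD-1 arm had a less even repertoire than PTX+aPD-1, with more NKT-associated segments. Clonality was 0.183 ± 0.135 (n = 14) against 0.0973 ± 0.0135 (n = 9), with 12 of 14 above (exact permutation adjusted p = 0.0393), and the NKT-associated list was at 24.5% ± 3.43 against 20.1% ± 2.82 (13 of 14 above, exact permutation adjusted p = 0.0209). TRBV1 was at 17.3% ± 4.55 against 13.3% ± 1.85, TRBV15 at 0.274% ± 0.398 against 1.35% ± 1.98 and TRBV12-1 at 1.62% ± 2.17 against 2.02% ± 1.25, with 0 of 33 segments past limma's threshold and 5 at unadjusted p under 0.05. TRBV13-2 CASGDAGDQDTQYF was in 7 of 14 mice against 0 of 9 (Fisher's exact adjusted p = 0.152). Within block B, which holds 7 and 9 of these libraries, it was in 0 of either, the difference in clonality was 0.0621 (exact permutation adjusted p = 0.398) and that in NKT-associated segments 3.69 percentage points (exact permutation adjusted p = 0.343). The list also missed the threshold without the deletion-list segments (3.73, exact permutation adjusted p = 0.224, range over alternatives 0.224 to 0.343). Without R replicate 7 the difference in clonality was 0.0541. Against PLX+PTX, the arm passed in no measure, with clonality at 0.183 ± 0.135 against 0.126 ± 0.0256 (8 of 14 above, permutation adjusted p = 0.282), log2 clonotypes at 8.96 ± 1.71 against 8.95 ± 1.40 and expanded share at 36.1% ± 25 against 26.7% ± 20.3. Of 33 segments 0 passed limma's test and 2 had an unadjusted p under 0.05, TRBV12-1 (1.62% ± 2.17 against 2.32% ± 1.66) and TRBV23 (0.936% ± 0.553 against 1.40% ± 0.646), followed by TRBJ1-4 (3.35% ± 1.37 against 2.27% ± 1.10).

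Within the PLX+PTX+aPD-1 arm, mice labelled R had a more clonal repertoire than mice labelled NR. Clonality was 0.257 ± 0.162 against 0.108 ± 0.0225 (n = 7 and 7), with 7 of 7 above the NR mean (exact permutation p = 0.00524, adjusted p = 0.0393). The most abundant clonotype took 2.36% to 65.0% of normalized values in R mice and 1.6% to 9.66% in NR mice. Chosen after their values were seen, TRBV4 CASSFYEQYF took 36.2% of normalized values and 15% of reads in R replicate 1 (exact 95% interval 13.5% to 16.5%), and TRBV30 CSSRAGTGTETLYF took 31.0% and 31.2% in R replicate 2 (interval 30.4% to 32.0%). Log2 clonotypes (8.87 ± 1.67 against 9.05 ± 1.89) and expanded share (41.6% ± 24.7 against 30.5% ± 26.0) did not pass by exact permutation. Segment use passed for 0 of 33 segments by limma, with 3 at unadjusted p under 0.05: TRBV20 (0.257% ± 0.571 against 0.756% ± 0.544), TRBV24 (23.5% ± 11.3 against 16.4% ± 3.30) and TRBV3 (6.61% ± 4.44 against 11.1% ± 2.60). TRBV2 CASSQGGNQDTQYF was in 5 of 7 R and 0 of 7 NR mice (Fisher's exact adjusted p = 0.315). Within blocks the difference in clonality was 0.145 (exact permutation adjusted p = 0.118), at 0.129 in block B and 0.160 in block C. With 3 and 4 mice the smallest exact permutation p is 0.0571, so neither block alone could reach the threshold. By read counts the difference was 0.115 (exact permutation adjusted p = 0.0564, range over alternatives 0.0258 to 0.673). Without R replicate 7, in which TRBV13-2 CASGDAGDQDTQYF dominated, it was 0.0933 (exact permutation adjusted p = 0.0404).

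At d95, the 4 PLX+PTX+aPD-1 libraries had 0 clonotypes of TRBV13-1, a deletion-list segment, against 0.321% ± 0.0725 in the 3 PTX libraries (limma adjusted p = 0.000344, 4 of 4 below), the 1 of 28 segments past the threshold among 6 at unadjusted p under 0.05. TRBJ1-3 (0.831% ± 0.356 against 1.82% ± 0.337) and TRBV2 (5.96% ± 1.15 against 10.1% ± 2.38) came next and did not pass. With 120 to 389 clonotypes in a PLX+PTX+aPD-1 library, a share of this size is about 1 clonotype, and with a pseudocount of 0.5 the call ended (limma adjusted p = 0.0663, range over alternatives 0.000112 to 0.212). Clonality was 0.156 ± 0.00970 against 0.129 ± 0.0311, log2 clonotypes 7.90 ± 0.74 against 9.17 ± 0.77, expanded share 52.7% ± 13 against 24.3% ± 21.7, and the NKT-associated list 38.1% ± 7.24 against 28% ± 1.23. With 4 and 3 mice the smallest exact permutation p is 0.0571, so these could not reach the threshold.

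Of the other lists, the superantigen-reactive segments, the deletion list and the TRBJ2 cluster passed in 0 of 13 comparisons by permutation, with 1 comparison at an unadjusted p under 0.05, that of the TRBJ2 cluster for PTX. Superantigen-reactive segments, which include those whose T cells are deleted by endogenous mouse mammary tumour virus products, were at 22.1% ± 3.86 in untreated tumours and 20.1% ± 1.13 in FVBN mice. Of these segments, TRBV12-1, TRBV12-2, TRBV13-3, TRBV15, TRBV16 and TRBV17 are also on the deletion list, and TRBV19, TRBV26, TRBV29 and TRBV31 are not. Without the deletion-list segments the list was at 17.5% ± 3.14 in untreated tumours and 16.3% ± 1.62 in FVBN mice of d80. Sharing of clonotypes was low. The mean Morisita-Horn index between mice of a group was 0.00466 in untreated tumours and 0.0109 in FVBN mice, and 0 of 13 comparisons passed by permutation, with 1 at unadjusted p under 0.05. That was PLX at 0.0400 against 0.00466 (permutation p = 0.0116, adjusted p = 0.151). Without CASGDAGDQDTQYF, an omission chosen after seeing the data, PLX was at 0.0326 (permutation p = 0.0282), and by the Jaccard index, which leaves out abundance, at 0.00512 against 0.00324 (permutation p = 0.103).

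**Figure D4:**
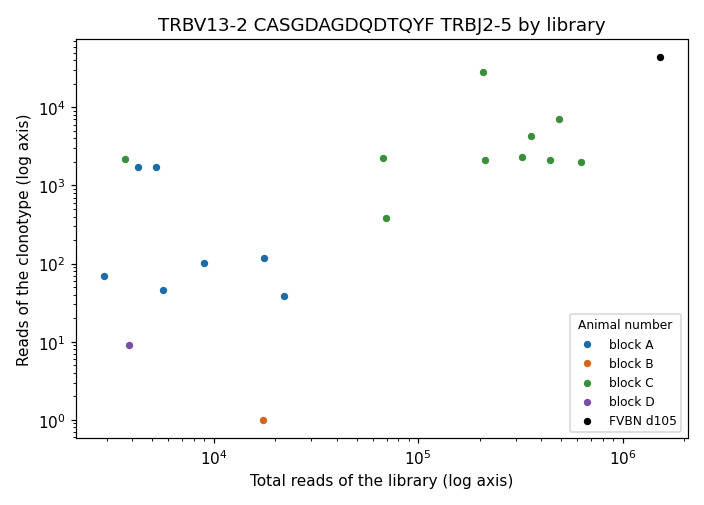
Reads of TRBV13-2 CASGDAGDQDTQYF TRBJ2-5 against the total reads of each of the 20 libraries that hold it, both on log axes, coloured by block of animal numbers. Block C libraries with 3694 and 622463 total reads hold 2155 and 2016 reads of it.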

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

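What each explanation of the patterns weighed here would predict was written only after the result was seen. Chosen only after the result was seen were also the omission of the deletion-list segments, alone or with thinning or blocks, the counts of nucleotide sequences and a comparison of the same mice at full depth, added once the thinned value was known. Thinning and permutation within blocks were set in advance, and the far samples come from a fixed rule. In 6 of 36 groups and measures checked, 1 sample lay far from the others of its group by Dixon's ratio, where chance gives about 1 in 20. Groups of more than 10 libraries (PTX, PLX+PTX and PLX+PTX+aPD-L1 of d105) were not checked, so far samples in them are not listed. The clonality of R replicate 7 was 0.588, where the next R mouse was at 0.308. PTX+aPD-L1 replicate 6 lay far in both clonality (0.243, next 0.149) and expanded share (29.97%, next 16.7%). The clonality of aPD-L1 replicate 5 was 0.205 (next 0.142). The deletion-list segments made up 25.4% of clonotypes in PTX+aPD-1 replicate 2 (next 10%) and 22.3% in untreated replicate 4 (next 14.2%). The FVBN library of d105, which enters no main comparison, held 44367 reads of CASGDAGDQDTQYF, against 0 in the FVBN libraries of d80.

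Higher clonality in mice labelled R than NR was set against technical explanations. Without the deletion-list segments the difference was 0.0886 (R higher, exact permutation adjusted p 0.0258, range over alternatives 0.0258 to 0.673), against 0.148 with them, so those segments make up part of it but not the whole. Without them and within blocks it was 0.094 (exact permutation p 0.018, adjusted p 0.108). The difference did not shrink, and the call ended with the adjustment over the comparisons. Thinned and without those segments it was 0.0496 (exact permutation p 0.23, 5 against 5 mice), and the same mice at full depth gave 0.0619 (p 0.0714), so the loss of mice alone takes most of the drop and depth cannot be told apart from the label with so few mice. A biological difference between R and NR mice stays open as a hypothesis, and R replicate 7 carries much of the size.

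The clonotype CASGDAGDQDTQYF was in 20 libraries, in all of them as the same nucleotide sequence. Shared receptors made separately in each mouse usually differ in nucleotides: the 6 amino acid clonotypes outside the deletion list in at least as many libraries had a median of 11.5 nucleotide sequences and at least 7, which argues against separate recombination. Carry-over of 1 sequence between libraries may explain it, but the 20 libraries with 1 sequence are the observation itself and do not test it. In block C, 6 of the 10 libraries held 2016 to 2317 reads of it at totals of 3694 to 622463, the others 388 to 28065. A shared source other than carry-over was not tested. No other biological explanation was tested, and PLX clonality, R replicate 7 and the shared clonotypes of PLX all include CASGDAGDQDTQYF. A single nucleotide sequence is not particular to it. TRBV17 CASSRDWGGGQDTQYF, also called for PLX, had 1 over all files, as did TRBV13-3 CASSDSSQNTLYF and TRBV12-1 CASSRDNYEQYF. Leaving out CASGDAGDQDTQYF alone keeps these in.

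More clonotypes in PTX+aPD-L1 than in PTX were set against depth and blocks. Thinned to the same reads the difference in log2 clonotypes was 1.05 (permutation p 0.000176), and within block A, the block with both arms, 1.17 (p 0.00643), against 1.36 as reported. Neither alone takes away the difference, though within blocks the adjusted p was 0.0684 (range over alternatives 0.00229 to 0.22). Thinning evens out reads and not the amount of DNA or T cells in a sample, which the labels do not give. More T cells, a wider repertoire or more DNA per library may each stand behind it, and these data cannot part them.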

How the results depend on the processing

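Tests chosen only after the result was seen were the omission of the deletion-list segments (alone, thinned or within blocks), the omission of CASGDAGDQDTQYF, the files' other normalized value, the lists, the F tests over all arms and the shared clonotypes within blocks, and the omission of single replicates outside d95. With 0 rows not marked productive, that alternative was not run. Read counts leave the number of clonotypes as it is and were not listed for it. No paired analysis was possible, since replicate numbers tie no mouse to another. Over all alternatives but single omissions, clonality kept its direction and side of the threshold in 126 of 181 values. The expanded share did in 144 of 181, log2 clonotypes in 111 of 142 and the lists in 95 of 117. Shared clonotype calls did in 45 of 49 and overlap in 23 of 27. Segment calls moved in 24 of 129. Named segments kept their direction and side of the threshold in 346 of 366 values, with 11 newly past the threshold, 7 no longer past it and 2 turned.

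Of the differences past the threshold as reported, 0 turned. Fewer clonotypes in MMTV-PyMT than FVBN held in 8 of 9 alternatives (-1.82 to -0.79, adjusted p 0.00238 to 0.0559), the larger expanded share in 9 of 12 (8.23 to 19.4) and the higher clonality in 5 of 12 (0.0144 to 0.0415). For PTX+aPD-L1 against PTX, more clonotypes held in 7 of 11 (0.93 to 1.58) and the smaller expanded share in 6 of 14 (-15.1 to -7.22). Fewer clonotypes with PLX held in 4 of 11 (-1.60 to -0.017). There permutation within blocks, counted as a miss, changed only the adjustment. Some misses, named below, had too few mice to pass. Clonality held in 4 of 14 for PTX+aPD-1 against PTX (-0.0795 to -0.00364), 5 of 14 for PLX+PTX+aPD-1 against PTX+aPD-1 (0.0286 to 0.11) and 5 of 15 for R against NR (0.0496 to 0.16). The MAIT-associated list with PLX missed the threshold in the only alternative that tests it, since permutation within blocks leaves those mice as they are. TRBJ2-3 with aPD-L1 held in 5 of 10 (-0.72 to -0.38). At d95 the call of TRBV13-1 ended in 6 of 9 alternatives, in 4 of which the segment dropped out. Its difference was -2.06 to -0.71 in the other 5, of which the fit of only the 2 groups and the block covariate leave the d95 fit as it is.

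The differences below, test group minus control, turned direction or changed their side of the threshold, and the cause was not tested. With read counts in place of normalized values, the expanded share turned for PTX against untreated (-1.34). In clonality, PLX+PTX against untreated (0.00305) and PLX+PTX+aPD-L1 against PLX+PTX (-0.00303) turned. For the expanded share, PTX+aPD-L1 against PTX (-10.6) and MMTV-PyMT against FVBN (16.9) missed the threshold. Clonality missed the threshold for PTX+aPD-1 against PTX (-0.0273), PLX+PTX+aPD-1 against PTX+aPD-1 (0.0698), R against NR (0.115) and MMTV-PyMT against FVBN (0.0172). With clonotypes of at least 2 reads, the expanded share turned for PTX against untreated (-0.0288). For log2 clonotypes, PLX+PTX against untreated (0.067) turned. Log2 clonotypes missed the threshold for PLX against untreated (-0.69) and PTX+aPD-L1 against PTX (1.26). In clonality, PTX+aPD-1 against PTX (-0.0369), PLX+PTX+aPD-1 against PTX+aPD-1 (0.0852), R against NR (0.15) and MMTV-PyMT against FVBN (0.0182) did not pass. Segment calls came to other numbers for PTX+aPD-1 against PTX (1) and d95 PLX+PTX+aPD-1 against PTX (0). With clonotypes merged by amino acids, log2 clonotypes missed the threshold for PLX against untreated (-0.94). In clonality, MMTV-PyMT against FVBN (0.0235) did not pass. Thinned to 2541 reads and computed on those reads, log2 clonotypes turned for PTX against untreated (-0.024). Clonality turned for PLX+PTX+aPD-L1 against PLX+PTX (-0.00336). In the expanded share, PTX+aPD-1 against PTX (-1.34) turned. For the expanded share, PTX+aPD-L1 against PTX (-11.2) and MMTV-PyMT against FVBN (16) missed the threshold. Clonality missed the threshold for PTX+aPD-1 against PTX (-0.0265), PLX+PTX+aPD-1 against PTX+aPD-1 (0.065) and R against NR (0.112). With the files' other normalized value, clonality missed the threshold for PTX+aPD-1 against PTX (-0.0351) and MMTV-PyMT against FVBN (0.0212). Without the deletion-list segments, the expanded share turned for PTX against untreated (-1.53). Clonality turned for PLX against untreated (-0.0262). In NKT-associated segments, PTX against untreated (-0.674) and R against NR (-1.36) turned. For MAIT-associated segments, PTX against untreated (0.325), PTX+aPD-L1 against PTX (0.429) and R against NR (-0.576) turned. MMTV superantigen-reactive segments turned for PTX against untreated (0.0378) and PLX+PTX+aPD-1 against PTX+aPD-1 (0.0242). In TRBJ2 cluster segments, PLX+PTX against PTX (0.0237) and R against NR (-0.0982) turned. For log2 clonotypes, PLX against untreated (-1.01) missed the threshold. MAIT-associated segments missed the threshold for PLX against untreated (3.35). In NKT-associated segments, PLX+PTX+aPD-1 against PTX+aPD-1 (3.73) did not pass. Segment calls came to other numbers for d95 PLX+PTX+aPD-1 against PTX (0). Without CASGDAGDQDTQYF, clonality turned for PLX against untreated (-0.0198). Thinned and without the deletion-list segments, clonality turned for PTX against untreated (-0.000907), PLX against untreated (-0.0235) and aPD-L1 against untreated (-0.00182). For the expanded share, PTX against untreated (-6.61) turned. Log2 clonotypes missed the threshold for PLX against untreated (-0.57). In the expanded share, PTX+aPD-L1 against PTX (-8.04) did not pass. For clonality, PTX+aPD-1 against PTX (-0.0244), PLX+PTX+aPD-1 against PTX+aPD-1 (0.0286) and R against NR (0.0496) missed the threshold. By the Gini index, clonality turned for PTX against untreated (-0.013), PLX against untreated (-0.043) and PTX+aPD-L1 against PTX (0.0117). In clonality, MMTV-PyMT against FVBN (0.0144) did not pass. By the share of the 10 most abundant clonotypes, the expanded share turned for PLX+PTX against PTX (-0.4998), PLX+PTX+aPD-L1 against PLX+PTX (0.284) and PTX+aPD-1 against PTX (-1.31). The expanded share missed the threshold for PTX+aPD-L1 against PTX (-7.22). By medians, clonality turned for PTX against untreated (-0.0137), PLX against untreated (-0.0141), PLX+PTX against untreated (0.00116), PLX+PTX against PTX (0.0148) and PTX+aPD-L1 against PTX (0.0014). For log2 clonotypes, PTX against untreated (-0.15) and PLX+PTX+aPD-1 against PLX+PTX (-0.22) turned. The expanded share turned for PTX against untreated (-1). In clonality, PTX+aPD-1 against PTX (-0.0148), PLX+PTX+aPD-1 against PTX+aPD-1 (0.032), R against NR (0.0877) and MMTV-PyMT against FVBN (0.0164) did not pass. Among libraries of at least 500 clonotypes, clonality turned for PLX against untreated (-0.0315). Log2 clonotypes turned for PLX+PTX against untreated (0.66), PLX+PTX against PTX (0.30) and PLX+PTX+aPD-L1 against PLX+PTX (-0.19). In the expanded share, PLX+PTX against untreated (-5.92), PLX+PTX against PTX (-11.8), PLX+PTX+aPD-L1 against PLX+PTX (4.32) and PTX+aPD-1 against PTX (-14.1) turned. For TRBV20 log2 difference, PLX+PTX against PTX (0.19) turned. Log2 clonotypes missed the threshold for PLX against untreated (-0.017), PTX+aPD-L1 against PTX (0.93) and MMTV-PyMT against FVBN (-0.91). In the expanded share, PTX+aPD-L1 against PTX (-12.4) and MMTV-PyMT against FVBN (8.79) did not pass. For clonality, PTX+aPD-1 against PTX (-0.076), PLX+PTX+aPD-1 against PTX+aPD-1 (0.0582), R against NR (0.0558) and MMTV-PyMT against FVBN (0.0246) missed the threshold. Segment calls came to other numbers for PLX against untreated (2), PLX+PTX+aPD-1 against PLX+PTX (1), PLX+PTX+aPD-1 against PTX+aPD-1 (1) and R against NR (1). The cut at 500 picks libraries by the measured number itself and leaves 2 PLX, 2 PTX+aPD-1, 3 R and 3 NR. PLX, R against NR and PLX+PTX+aPD-1 against PTX+aPD-1 could not pass by permutation.

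Within blocks of animal numbers, the F test of the expanded share over all arms did not pass (2.33, permutation adjusted p 0.141), and the cause of the changes was not tested. Permuted within blocks, the expanded share turned for PTX against untreated (-1.32), PLX+PTX against untreated (-4.91), PLX+PTX+aPD-L1 against PLX+PTX (5.26) and PTX+aPD-1 against PTX (-1.31). In log2 clonotypes, PLX+PTX against untreated (0.15), PTX+aPD-1 against PTX (0.11), PLX+PTX+aPD-1 against PLX+PTX (-0.53) and PLX+PTX+aPD-1 against PTX+aPD-1 (-0.67) turned. For MAIT-associated segments, PTX+aPD-L1 against PTX (0.474) and PTX+aPD-1 against PTX (-0.902) turned. MMTV superantigen-reactive segments turned for PLX+PTX+aPD-L1 against PLX+PTX (0.0128) and PLX+PTX+aPD-1 against PTX+aPD-1 (1.14). In TRBJ2 cluster segments, PLX+PTX+aPD-L1 against PLX+PTX (0.348) and R against NR (-0.62) turned. For Vbeta-a deletion segments, PLX+PTX+aPD-1 against PLX+PTX (0.298) and PLX+PTX+aPD-1 against PTX+aPD-1 (5.07) turned. NKT-associated segments turned for R against NR (-0.154). In log2 clonotypes, PLX against untreated (-0.97) and PTX+aPD-L1 against PTX (1.17) did not pass. For the expanded share, PTX+aPD-L1 against PTX (-12.4) missed the threshold. Clonality missed the threshold for PTX+aPD-1 against PTX (-0.00364), PLX+PTX+aPD-1 against PTX+aPD-1 (0.0621) and R against NR (0.145). In NKT-associated segments, PTX+aPD-1 against PTX (-3.27) and PLX+PTX+aPD-1 against PTX+aPD-1 (3.69) did not pass. Shared clonotype calls came to other numbers for PTX+aPD-1 against PTX (0). Within blocks and without the deletion-list segments, the expanded share turned for PTX against untreated (-3.72), PLX+PTX against untreated (-5.72), PLX+PTX+aPD-L1 against PLX+PTX (4.28) and PTX+aPD-1 against PTX (-1.25). In clonality, PLX against untreated (-0.0262) turned. For log2 clonotypes, PLX+PTX against untreated (0.17), PTX+aPD-1 against PTX (0.098), PLX+PTX+aPD-1 against PLX+PTX (-0.54) and PLX+PTX+aPD-1 against PTX+aPD-1 (-0.76) turned. Log2 clonotypes missed the threshold for PLX against untreated (-1.01) and PTX+aPD-L1 against PTX (1.22). In the expanded share, PTX+aPD-L1 against PTX (-12.9) did not pass. For clonality, PTX+aPD-1 against PTX (-0.00509), PLX+PTX+aPD-1 against PTX+aPD-1 (0.0689) and R against NR (0.094) missed the threshold. In block A alone, the expanded share turned for PTX against untreated (-1.32), PLX+PTX against untreated (-4.91), PLX+PTX against PTX (-3.58) and PLX+PTX+aPD-L1 against PLX+PTX (5.26). In log2 clonotypes, PLX+PTX against untreated (0.15) turned. For the expanded share, PTX+aPD-L1 against PTX (-12.4) missed the threshold. In block B alone, clonality turned for PLX+PTX against PTX (0.0197). In log2 clonotypes, PTX+aPD-1 against PTX (0.11), PLX+PTX+aPD-1 against PLX+PTX (-0.41) and PLX+PTX+aPD-1 against PTX+aPD-1 (-0.67) turned. For the expanded share, PTX+aPD-1 against PTX (-1.31) turned. Clonality missed the threshold for PTX+aPD-1 against PTX (-0.00364) and PLX+PTX+aPD-1 against PTX+aPD-1 (0.0621). R against NR (0.129) could not pass. In block C alone, clonality could not pass for R against NR (0.16). With block as a covariate, TRBV12-1 log2 difference turned for PLX+PTX+aPD-1 against PTX+aPD-1 (0.46). Segment calls came to other numbers for aPD-L1 against untreated (0) and PTX+aPD-L1 against PTX (1).

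For segments, shared clonotypes and overlap, the cause was not tested. By share of normalized values, segment calls came to other numbers for PLX against untreated (2), aPD-L1 against untreated (0), PLX+PTX+aPD-1 against PLX+PTX (4), PLX+PTX+aPD-1 against PTX+aPD-1 (5), R against NR (6) and d95 PLX+PTX+aPD-1 against PTX (0). By share of reads, segment calls came to other numbers for PLX against untreated (2), aPD-L1 against untreated (0), PLX+PTX+aPD-1 against PLX+PTX (4), PLX+PTX+aPD-1 against PTX+aPD-1 (1), R against NR (4) and d95 PLX+PTX+aPD-1 against PTX (0). At a pseudocount of 0.5 or with segments of at least 1%, segment calls came to other numbers for d95 PLX+PTX+aPD-1 against PTX (0). With only the 2 groups in the fit, segment calls came to other numbers for aPD-L1 against untreated (0). By CDR3 amino acids alone, shared clonotype calls came to other numbers for PTX+aPD-L1 against PTX (1), and with at least 2 reads for PLX against untreated (6). Among clonotypes in at least 10% of mice, shared clonotype calls came to other numbers for PLX against untreated (1) and PTX+aPD-1 against PTX (0). By the Jaccard index, overlap turned for PTX against untreated (-0.000858), PTX+aPD-L1 against PTX (0.00154), PLX+PTX+aPD-L1 against PLX+PTX (0.000783) and PTX+aPD-1 against PTX (-0.000401). As reported, segment calls are 1 for aPD-L1 against untreated, 1 at d95 and 0 elsewhere, and shared clonotype calls 5 for PLX and 1 for PTX+aPD-1 against PTX.

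Leaving out 1 library at a time, the range for clonality, MMTV-PyMT vs FVBN was 0.0193 to 0.0271. The call ended without untreated replicates 4 (0.0228), 5 (0.0235), 6 (0.0219), 11 (0.0193) and 12 (0.0218) and FVBN replicates 1 (0.0245), 2 (0.0226), 3 (0.0242), 4 (0.0212) and 6 (0.021), at adjusted p up to 0.0966. For clonality, PTX+aPD-1 vs PTX the range was -0.0431 to -0.0218, and the call ended without PTX+aPD-1 replicates 5 (-0.0379), 6 (-0.0369), 7 (-0.0372) and 9 (-0.0384) and PTX replicates 1 (-0.0381), 7 (-0.0218), 11 (-0.0385) and 16 (-0.0353), at adjusted p up to 0.073. For number of clonotypes, PLX vs Untreated it was -1.14 to -0.88, and the call ended without PLX replicates 1 (-0.91), 2 (-0.89), 4 (-0.93), 5 (-1.005), 6 (-0.88), 7 (-1.002), 9 (-0.92) and 11 (-0.92) and untreated replicates 2 (-0.91), 3 (-0.95), 5 (-0.94), 6 (-0.89), 9 (-0.89), 11 (-0.94) and 12 (-0.996), at adjusted p up to 0.0892. The other calls of these measures held in each single omission. Clonality of R against NR ran from 0.0933 (without R replicate 7) to 0.171, and that of PLX+PTX+aPD-1 against PTX+aPD-1 from 0.0541 (without R replicate 7) to 0.0931. Log2 clonotypes ran over 1.20 to 1.57 for PTX+aPD-L1 against PTX and -1.52 to -1.13 for MMTV-PyMT against FVBN, and the expanded share over -16.6 to -11.9 and 14.4 to 18.6. The cause was not tested.

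At d95, single omissions gave 0.0164 to 0.0449 for clonality, -1.59 to -0.84 for log2 clonotypes and 18.7 to 40.1 for the expanded share, in a design too small to pass. Segment calls ran from 0 to 2. They were 2 without PLX+PTX+aPD-1 replicate 1 or 3 or PTX replicate 2, and 0 without PTX replicate 3. Without PTX replicate 3, TRBV13-1 fell under the filter, and in the other omissions its difference was -2.14 to -2.06. TRBJ1-3 log2 difference, d95 PLX+PTX+aPD-1 vs PTX ran over -1.33 to -0.92, past the threshold without PLX+PTX+aPD-1 replicate 3 (-1.33, limma adjusted p 0.0292, range over omissions up to 0.343), and TRBV2 over -0.93 to -0.59.

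Depth limits what the number of clonotypes can show: 55 of 118 libraries hold fewer than 500 clonotypes, and 12 hold fewer than the 2541 reads used for thinning. Recovery of changed segments by limma was simulated for PTX+aPD-L1 against PTX alone, at 66% of 2-fold changes among 14 segments.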

Other observations

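The test of near-copies was chosen only after the result was seen, while those of the other splits and of the reads left out were set before it. The FVBN library of d105 had a clonality of 0.0843, 17300 clonotypes, an expanded share of 2.78% and 0.457% of clonotypes in deletion-list segments. The untreated MMTV-PyMT library of d80 had a clonality of 0.119, 271 clonotypes, an expanded share of 36.3% and 22.9% of clonotypes in deletion-list segments.

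Splits of the same mice, the real one included, were fitted with limma for each comparison, 100 of them, or all 35 at d95. For aPD-L1 against untreated, 2 of 100 splits, the real one among them, gave as many calls as the real one (1, highest other 1). Chance is unlikely for this comparison taken alone, but it is not excluded. Over all 13 comparisons chance is less unlikely, since simulations without a change, run for PTX+aPD-L1 against PTX, gave a call in 10% of cases. The count of calls is also 0 with only the 2 groups in the fit and by share of normalized values or reads. Block as a covariate gives the same fit as the 2 groups alone, since both lie in block A. At d95, 4 of 35 splits gave as many as the real 1 (highest other 2), so chance cannot be excluded. In the other comparisons the real count was 0, which all 100 splits reach by design, so the splits decide nothing there. Their highest other counts were 0 for PTX against untreated and PTX+aPD-L1 against PTX, 1 for PLX+PTX against PTX, PTX+aPD-1 against PTX and MMTV-PyMT against FVBN, and 2 for PLX and PLX+PTX against untreated. They were 3 for PLX+PTX+aPD-1 against PTX+aPD-1, 4 for R against NR and for PLX+PTX+aPD-L1 against PLX+PTX, and 6 for PLX+PTX+aPD-1 against PLX+PTX.

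Libraries from which the authors left out more reads held more deletion-list clonotypes, as predicted before the test. Spearman's rho within blocks was 0.781 (n = 117, permutation p 2e-05, the smallest possible), and 0.841 over all 118 libraries. It was 0.851 in block A, 0.776 in block B and 0.893 in the FVBN libraries of d80 (exact p 0.0123). In block C it was 0.358 (permutation p 0.314), so it was not shown there. In block D it was 0.612 (exact p 0.286). Nearly all libraries there kept 100% of reads, so the test could not reach the threshold and decides nothing. One hypothesis is that these clonotypes may be remnants of reads the authors removed, which a rho of 0.781 fits but does not establish.

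Clonotypes 1 base from the receptor sequences of 2 transgenic lines used in mouse immunology were in 73 files (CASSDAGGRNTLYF, as in P14) and 75 files (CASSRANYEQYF, as in OT-I), while the central nucleotide form of each was in 0 of 118 files. The amino acid clonotype TRBV13-3 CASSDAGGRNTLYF itself was in 47 files under other nucleotide sequences. Errors of receptor sequences that were removed from the files may explain this, but the test set for it, the density of clonotypes 1 base away over that 2 bases away, gave at lowest 27 where 10 ordinary clonotypes had a median of 30.8, so it decides nothing. Of the possible sequences 1 base away, 25.4% and 28.7% were seen, against at most 12.1% for the ordinary clonotypes. Among the near-copies are shared clonotypes that passed for PLX or PTX+aPD-1: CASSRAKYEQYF had a sequence 1 base away in 61 of its 61 files and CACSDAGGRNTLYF in 48 of 52. What those calls mean is therefore open as well.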
